A study of Mus musculus with 4 samples.

How the data were processed

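Macrophages were sorted from the BM and spleen of C57BL/6J mice, normal or 18 days after transplantation of GFP+ MLL-AF9 leukaemia cells without irradiation, and total RNA was extracted with a QIAGEN RNeasy Mini kit, per the labels' protocols. Small RNA libraries were sequenced on an Illumina HiSeq instrument, per the labels. The markers of the sort, and whether libraries of the 2 tissues came from the same mice, are not given in the sources used here. The aligner, the counting tool, the genome build and the miRNA annotation are likewise not given in the sources used here.

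The deposited table holds read counts per miRNA for 4 libraries and 847 rows, 804 with names of known mouse miRNAs and 43 with names of predicted miRNAs. The predicted rows held between 0.0193% and 0.0915% of the reads of a library. The deposited TPM values are named so per the file headers, and each equalled the count divided by the total of its library times 1000000, with no length term. TPM was used only for this check, and all analysis started from the counts. Of rows with at least 100 counts over the 4 libraries, 7 had counts that matched those of another row in all 4 libraries within 3% or 2 counts. Examples are miR-142b and miR-142a-3p, or miR-1b-5p and miR-1a-3p. The same reads thus seem to appear more than once in the deposited counts, and the cause was not tested. For miR-126b-3p and miR-126a-5p, which also matched, the hairpins overlap on opposite strands of chromosome 2. Rows with fewer counts were not searched, since small counts meet this tolerance easily, and some of them also match, such as miR-338-3p and miR-3065-5p. The row miR-486b-3p matched miR-486a-3p in this way, so the level of miR-486a-3p is uncertain for the same reason. Just outside the tolerance, miR-486a-5p had 913, 3466, 1779 and 1340 counts in normal BM, normal spleen, AML BM and AML spleen. For miR-486a-3p these were 889, 3361, 1759 and 1304. The same reads may thus enter the erythroid list and its read share more than once.

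Each sample was assigned to its group from its title: normal BM, normal spleen, AML BM and AML spleen, 1 library each. Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.00, 0.900, 1.03 and 1.07 for normal BM, normal spleen, AML BM and AML spleen. With 1 library per group no test across replicates exists for a pair of libraries, so each comparison gives the ratio of scaled counts with a 95% exact conditional (Clopper-Pearson) interval. A miRNA was called different when the ratio was at least 2 or at most 0.5, the interval excluded 1 and the larger count was at least 30. A count of 0 entered as 3 counts, which gives a bound, and 3 counts corresponded to between 7.65 and 15.5 CPM of the scaled libraries. Reads carried no molecular identifiers in the files used, so intervals and bounds cover counting error only. Poisson counts were simulated for the AML BM against normal BM comparison (218 miRNAs with at least 30 counts), with no variation between mice or libraries beyond counting. Intervals covered the true ratio for 94.0%, 98.1% of 4-fold changes were recovered and 0 of 164 unchanged miRNAs were called. These figures thus say nothing about calls that variation between mice would cause.

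The additive model was fitted to 246 miRNAs with at least 30 counts in some library, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, and with DESeq2 1.42.0 and limma 3.58.1 (limma-trend, prior count 2) as alternatives. On counts simulated for the AML effect, at a dispersion of 0.1 (245 miRNAs tested) it recovered 96.9% of changes with a log2 fold of 2 and 100% with a log2 fold of 3. At the dispersion estimated here, 0.417 (260 miRNAs tested), it recovered 0% of both. Unchanged miRNAs called numbered 3 of 173 at a dispersion of 0.1 and 0 of 189 at 0.417. The p-values of this model count any difference of the AML effect between tissues as noise, and they measure only the spread between these libraries.

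The choices described here were fixed before the data were examined, except for 4 alternatives named in the closing section. There were 16 lists: erythroid, myeloid and pan-haematopoietic, inflammation-induced, alternative macrophage activation, lymphocyte, leukaemic blast and progenitor, miR-17~92 and its paralogous clusters, let-7, stromal and endothelial, miR-232724, miR-29, miR-30, miR-221, miR-222 and miR-34, Dlk1-Dio3, other tissues, and hypoxia. For a list with at least 3 members compared, the percentile of its median log2 ratio was taken among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Random lists drew each miRNA separately, whereas some lists hold both arms of a hairpin, such as those of miR-142a or miR-126a. Such members are not independent, so a percentile can look more extreme than the number of separate genes warrants. The miR-126a arms stand in both the blast and progenitor list and the stromal and endothelial list, and some members of the other-tissue list, such as miR-128-3p, are also expressed in blood cells. The rule for naming took the 10 most abundant miRNAs, the 8 highest and 8 lowest ratios of each AML comparison and the 5 highest and 5 lowest of each tissue comparison among those with at least 100 counts, up to 4 members of each list with the highest mean level, up to 5 per direction with the smallest p in each additive test, and the 5 highest and 5 lowest gaps between tissues. It took 101 miRNAs, not all of which are named in the text. Other members of a list are named where its count is given. Names carry the prefix mmu- in the table.

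Alternatives were DESeq2 size factors, total counts, totals without the 10 most abundant miRNAs of each library, a minimum of 1 or 100 counts, and a whole interval beyond 2-fold. For the additive model they were other scalings, filters, tests and a fit without the other factor. Hairpins were matched by name to GENCODE M21 on GRCm38, which is not known to be the build behind the counts. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.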

Results

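Small RNA was sequenced from macrophages sorted from the bone marrow (BM) and the spleen of C57BL/6J mice, either normal or 18 days after transfer of MLL-AF9 acute myeloid leukaemia (AML) cells. MLL-AF9 is a fusion of the MLL histone methyltransferase gene with AF9 that drives AML. The labels give an age of 6 to 8 weeks and a survival of 35 to 40 days, whereas the AML samples here were taken at 18 days. The stated purpose was to compare the microRNAs (miRNAs) of leukaemia-associated macrophages with those of macrophages at homeostasis. There were 4 libraries, 1 for each combination of tissue and state, so no difference below has a replicate check, and each statement compares libraries rather than conditions. The total count was 206652 in normal BM, 435492 in normal spleen, 271209 in AML BM and 180227 in AML spleen. Detected rows numbered 505, 680, 547 and 535 in the same order, out of 847. The 10 most abundant miRNAs of each library held 46.9% of its reads in normal BM, 57.4% in normal spleen, 50.4% in AML BM and 50.5% in AML spleen. The miRNAs with the highest mean level over the libraries were miR-92a-3p, miR-423-5p, miR-423-3p, let-7d-3p and miR-181a-5p, followed by miR-328-3p, let-7i-5p, miR-744-5p, miR-21a-5p and let-7a-5p. Levels are counts per 1000000 reads (CPM) of the scaled library, ratios are on the log2 scale with 95% exact conditional intervals in brackets, and these intervals cover counting error only.

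Macrophages of leukaemic BM had higher miR-142a-3p and miR-155-5p and lower miR-451a and muscle miRNAs than macrophages of normal BM. Of 216 miRNAs with at least 30 counts in the larger library, 29 were at least 2-fold higher in the AML BM library and 26 at least 2-fold lower. The myeloid and pan-haematopoietic list had 3 members compared, of which 2 were higher and 1 was neither, with a median log2 ratio of 1.39 that lay at percentile 99.3 of 10000 expression-matched random lists. The other-tissue list of liver, muscle, neuronal and epithelial miRNAs had 6 of 11 members lower and 1 higher, with a median of -1.17 at percentile 0.005.

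Among the miRNAs higher in AML BM, miR-155-5p, which inflammatory signalling induces in macrophages, had 100 counts against 14 in normal BM, a log2 ratio of 2.40 [1.59 to 3.32]. The haematopoietic miR-142a-3p stood at 606 CPM in AML BM and 149 CPM in normal BM, a log2 ratio of 2.02 [1.46 to 2.62], and miR-142b, whose row holds the same reads, gave the same value. The other arm, miR-142a-5p, had a log2 ratio of 0.93 and did not reach 2-fold, but stood at 1.07 on totals without the 10 most abundant miRNAs. The myeloid miR-223-5p was higher by 1.39 [0.89 to 1.92], while miR-223-3p had 12 and 10 counts and was too thinly covered to compare. The abundant miR-139-5p was 3.25-fold higher, at 26662 CPM against 8212 CPM, with a log2 ratio of 1.70 [1.62 to 1.78]. Further miRNAs at least 2-fold higher were miR-669c-5p (2.80), miR-8112 (1.70), miR-298-5p (1.56), miR-146b-5p (1.03) and miR-128-3p (1.08). From 5 counts in normal BM, miR-3470b was higher by 2.67 [1.34 to 4.36].

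The lymphocyte list had 2 of 5 members higher in AML BM and a median log2 ratio of 0.86 (percentile 96.8). Its members miR-181a-5p and miR-181b-5p were higher by 1.47 [1.41 to 1.54] and 1.02 [0.84 to 1.20]. Below 2-fold, miR-150-5p had a log2 ratio of 0.86, which passed 2-fold on totals without the 10 most abundant miRNAs, and miR-181d-5p one of 0.66, and miR-150-3p stood at -0.18. Reads of this list made up 1.69% of the normal BM library and 4.45% of the AML BM library. Of 5 inflammation-induced miRNAs, 2 were higher (miR-155-5p and miR-146b-5p), miR-9-5p was lower at -1.19, and 2 were neither. These were miR-21a-5p, the most abundant of the list, at -0.71 [-0.76 to -0.67] and miR-146a-5p at 0.13 [-0.04 to 0.31], which was also the list median (percentile 48.2).

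Among the miRNAs lower in AML BM, the erythroid miR-451a had a log2 ratio of -2.15 [-2.34 to -1.97], the lowest of the miRNAs with at least 100 counts. Its list neighbours miR-486a-5p and miR-486a-3p, whose counts lay close in every library, stood at 0.53 and 0.55, and miR-144-3p at -0.02. The muscle miRNAs miR-206-3p, miR-133a-3p and miR-1a-3p had log2 ratios of -1.93, -1.81 and -1.74, and miR-1b-5p, which shares the reads of miR-1a-3p, one of -1.73. The liver miRNA miR-122-5p stood at -1.17 [-1.29 to -1.04]. The stromal and endothelial list had 3 of 9 members lower (miR-214-3p, miR-199b-5p and miR-199a-5p) and a median of -0.77 (percentile 1.47). Its abundant members miR-143-3p and miR-126a-3p stood at -0.49 and -0.44. Reads of the other-tissue list made up 5.77% of the normal BM library and 2.72% of the AML BM library, and those of the stromal and endothelial list 3.24% and 2.31%. Within the miR-17~92 family, miR-20a-5p was lower at -1.20 and the other 10 members compared were neither, with a list median of 0.36 (percentile 85.1).

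None of the 10 members of the leukaemic blast and progenitor list differed 2-fold between AML BM and normal BM. This list holds HOX-embedded miRNAs such as miR-196b, miR-10a and miR-10b, and its median log2 ratio was -0.11, which turned positive with scaling on totals without the 10 most abundant miRNAs. Its member miR-196b-5p, known to be raised in MLL-rearranged leukaemia cells, had 196 and 80 counts and a log2 ratio of 0.86 [0.48 to 1.25]. No member of the let-7 (9 compared), miR-30 (7), miR-232724 (7), miR-221, miR-222 and miR-34 (4) or alternative activation (5) lists differed 2-fold. Their medians were -0.19, -0.49, 0.03, -0.18 and -0.05, and the last of these changed sign under the same scaling.

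Macrophages of leukaemic spleen had lower miR-146a-5p, miR-155-5p, miR-150-5p, miR-142a-3p and miR-92a-3p than those of normal spleen, and higher stromal, endothelial and muscle miRNAs. Of 216 miRNAs compared, 54 were at least 2-fold higher in the AML spleen library and 46 at least 2-fold lower. The stromal and endothelial list had 6 of 6 members higher with a median log2 ratio of 2.67 (percentile 99.96). These were miR-143-3p, miR-145a-5p and both arms of miR-199a and of miR-126a, so they are not independent members. The miR-17~92 family had 8 of 12 members lower with a median of -1.34 (percentile 0.1). The lymphocyte list had 4 of 5 members lower, with a median of -1.40 (percentile 1.51).

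Lower in AML spleen, miR-146a-5p, a feedback inhibitor of NF-kB signalling, stood at 4183 CPM against 17223 CPM in normal spleen, a log2 ratio of -2.04 [-2.15 to -1.94]. For miR-155-5p the log2 ratio was -2.09 [-2.42 to -1.79], from 95 and 824 counts. The lymphocyte miRNA miR-150-5p stood at 8687 CPM against 25275 CPM, a log2 ratio of -1.54 [-1.62 to -1.47], while the other arm, miR-150-3p, stood at 0.40. Its list neighbours miR-181d-5p, miR-181b-5p and miR-181a-5p were lower at -2.78, -1.40 and -1.14. The haematopoietic miR-142a-3p and miR-142a-5p were lower at -1.73 and -1.27, and miR-223-5p (10 and 36 counts) stood at -0.82. The most abundant miRNA of the normal spleen library, miR-92a-3p, had 166362 CPM there and 60833 CPM in AML spleen, a log2 ratio of -1.45 [-1.48 to -1.42]. Other members of its family were lower too, with log2 ratios of -1.98 for miR-17-3p, -1.36 for miR-25-5p, -1.33 for miR-106b-3p and -1.16 for miR-25-3p. The 4 members called neither were miR-17-5p and miR-93-5p (both -0.90), miR-20a-5p (0.16) and miR-106b-5p. The last had 39 counts in AML spleen against 61 in the larger normal spleen library, which is higher once scaled, by less than 2-fold. With DESeq2 size factors miR-17-5p and miR-93-5p passed 2-fold, both at -1.14. Further miRNAs lower in AML spleen were miR-185-3p (-2.80), miR-130b-5p (-1.85), miR-1839-5p (-1.75), miR-342-3p (-1.67) and miR-140-5p (-1.67).

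Higher in AML spleen, miR-381-3p, of the imprinted Dlk1-Dio3 region, had 82 counts against 10 and a log2 ratio of 4.06 [3.11 to 5.17], and miR-127-3p of the same region stood at 2.27 [1.87 to 2.68]. The stromal miRNAs miR-199a-3p, miR-143-3p and miR-145a-5p were higher by 2.74, 2.60 and 2.51, and the endothelial miR-126a-3p by 2.76. For miR-143-3p this was 13559 CPM against 2242 CPM. In the other-tissue list 7 of 9 members were higher and 2 were neither, with a median of 1.98 (percentile 99.3), among them miR-133a-3p (3.26), miR-1a-3p (2.41), miR-200a-3p (2.42), miR-206-3p (1.98) and miR-122-5p (1.54). Reads of the other-tissue list made up 0.658% of the normal spleen library and 2.58% of the AML spleen library, and those of the stromal and endothelial list 0.331% and 2.38%. The leukaemic blast and progenitor list had 6 of 8 members higher and 1 lower, with a median of 2.30 (percentile 99.6). Its higher members were miR-100-5p (2.97), miR-10b-5p (2.70), miR-10a-5p (1.90), miR-99a-5p (1.53) and both arms of miR-126a, which the stromal and endothelial list also holds. The lower member was miR-196b-5p, with 5 counts against 34 and a log2 ratio of -1.74 [-3.45 to -0.38].

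The abundant miR-21a-5p, of the inflammation-induced list, was higher in AML spleen by 1.44 [1.39 to 1.49], as was miR-9-5p by 2.57, so this list had 2 members higher and 2 lower of 5 compared and a median of -0.72 (percentile 23.9). In the miR-30 family 5 of 7 members were higher, led by miR-30a-5p at 2.33 [2.23 to 2.42], and the list median was 1.44 (percentile 93.1). The erythroid miR-451a was higher by 1.96 [1.70 to 2.22] while miR-486a-5p stood at -0.35. Of the same list, miR-144-3p had 2 counts in AML spleen against 25 in normal spleen, too few to be compared. Against the 36 counts of AML BM it was lower in AML spleen, at -3.63. In the let-7 family let-7a-5p was lower at -1.13, let-7e-5p was higher by 1.38 and the other 7 were neither, with a median of -0.64. The miR-232724 list had 2 of 7 members higher, with miR-27b-3p at 1.16, and a median of 0.08 that changed sign with DESeq2 scaling. The miR-221, miR-222 and miR-34 list had 2 of 4 higher, miR-34c-5p at 2.34 and miR-34a-5p at 1.25. Of 5 alternative activation miRNAs, 1 (miR-34a-5p) was higher, and the list median of -0.21 changed sign with scaling on total counts. Scaling moved the balance of this comparison: the split of 54 higher and 46 lower was 51 and 68 with DESeq2 size factors and 64 and 36 on total counts. All log2 ratios of AML spleen against normal spleen moved by -0.24 and by 0.25 under these scalings. On total counts 10 of the 100 calls ended, among them those of miR-181a-5p (-0.89), miR-25-3p (-0.91) and let-7a-5p (-0.88), and 10 others began. With DESeq2 size factors 3 calls ended, those of miR-27b-3p (0.92), miR-30c-5p (0.97) and miR-3473b (0.78), and 22 began, among them miR-223-5p (-1.06), let-7c-5p (-1.08) and let-7d-5p (-1.20), all lower.

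**Figure D1:**
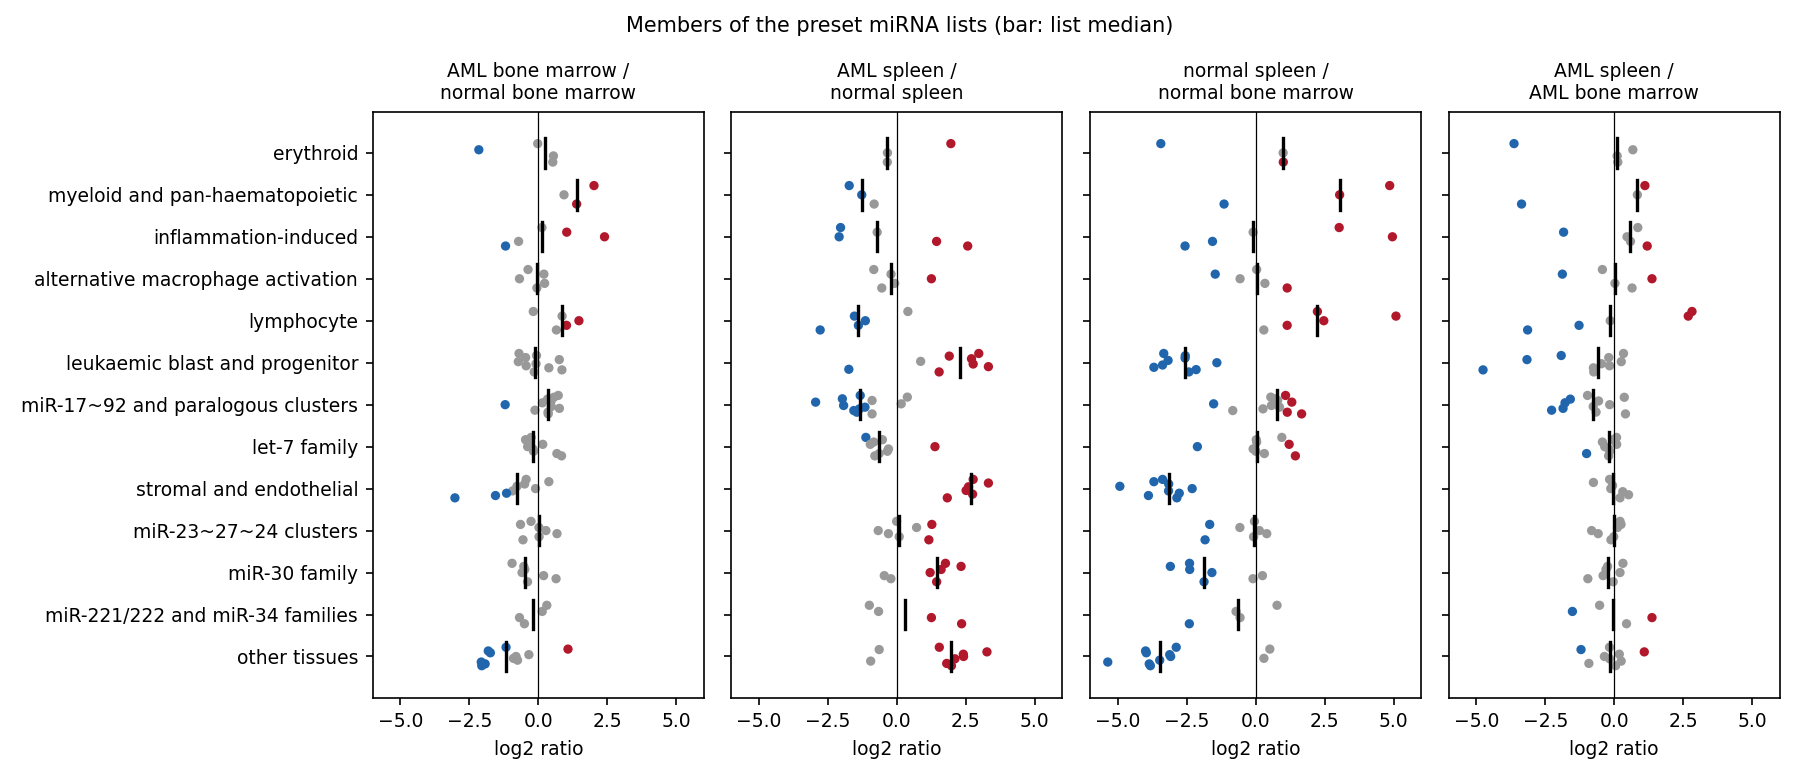
Log2 ratios of the members of 13 preset miRNA lists (rows) in the 4 comparisons (panels), with 1 point per miRNA that had at least 30 counts in the larger library. Red points were at least 2-fold higher in the first-named library, blue points at least 2-fold lower and grey points neither, and black bars are list medians, for example 2.67 for the stromal and endothelial list in AML spleen against normal spleen.

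The AML-to-normal ratios of the BM and the spleen ran in opposite directions. Over 144 miRNAs with at least 30 counts in every library, the log2 ratios had Pearson's r of -0.684 (interval from resampled counts -0.697 to -0.631) and Spearman's rho of -0.704 across miRNAs, which are not independent replicates. Their covariance was -0.687, and the 2 comparisons share no library. Each resample added counting noise to counts that already held it, which draws r toward 0. The resampled interval is therefore not a 95% confidence interval for r. Of 21 miRNAs at least 2-fold different in both tissues, 20 differed in opposite directions and 1, miR-3470b, was higher in both, a same-direction share of 4.76% (Wilson 95% interval 0.846% to 22.7%). The share was 9.09% (2 of 22) on total counts, 10.9% (5 of 46) with a minimum of 1 count and 0% (of 14) with a minimum of 100 counts. Of the 186 miRNAs compared in both tissues, 27 were higher and 11 lower in AML BM, and 49 were higher and 36 lower in AML spleen. Independent lists of these sizes would share 7.11 miRNAs higher in both, 2.13 lower in both, 5.23 higher in AML BM and lower in AML spleen, and 2.90 lower in AML BM and higher in AML spleen. The miRNAs higher in AML BM and lower in AML spleen numbered 11 and included miR-155-5p, miR-142a-3p, miR-181a-5p, miR-181b-5p, miR-185-3p and miR-92a-1-5p, of which miR-181a-5p lost its call in AML spleen on total counts. The miRNAs lower in AML BM and higher in AML spleen numbered 9 and included miR-451a, miR-1a-3p, miR-133a-3p, miR-206-3p, miR-122-5p, miR-9-5p and miR-6538. These counts hold miR-142b and miR-1b-5p, whose rows repeat the reads of miR-142a-3p and miR-1a-3p.

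The AML ratio of the spleen differed at least 4-fold from that of the BM for 69 of the 186 miRNAs, 40 with the spleen ratio above and 29 with it below. On the log2 scale the gap was 5.23 for miR-6538, 5.08 for miR-133a-3p, -4.49 for miR-155-5p and -6.57 for miR-185-3p, the last from 2 counts in normal BM and 8 in AML spleen. Across the 144 miRNAs, log2 levels of normal BM correlated with r of 0.946 with AML BM, 0.891 with AML spleen and 0.674 with normal spleen. Those of AML spleen had r of 0.918 with AML BM and 0.861 with normal spleen, and those of AML BM and normal spleen had r of 0.811. AML spleen was thus closer to both BM libraries than to normal spleen by this measure. The muscle miRNA miR-1a-3p stood at 29160 CPM in normal BM, 8752 CPM in AML BM, 9946 CPM in AML spleen and 1875 CPM in normal spleen. With the other-tissue and stromal miRNAs left out, an alternative chosen after the values were seen, r was -0.644 over 129 miRNAs.

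**Figure D2:**
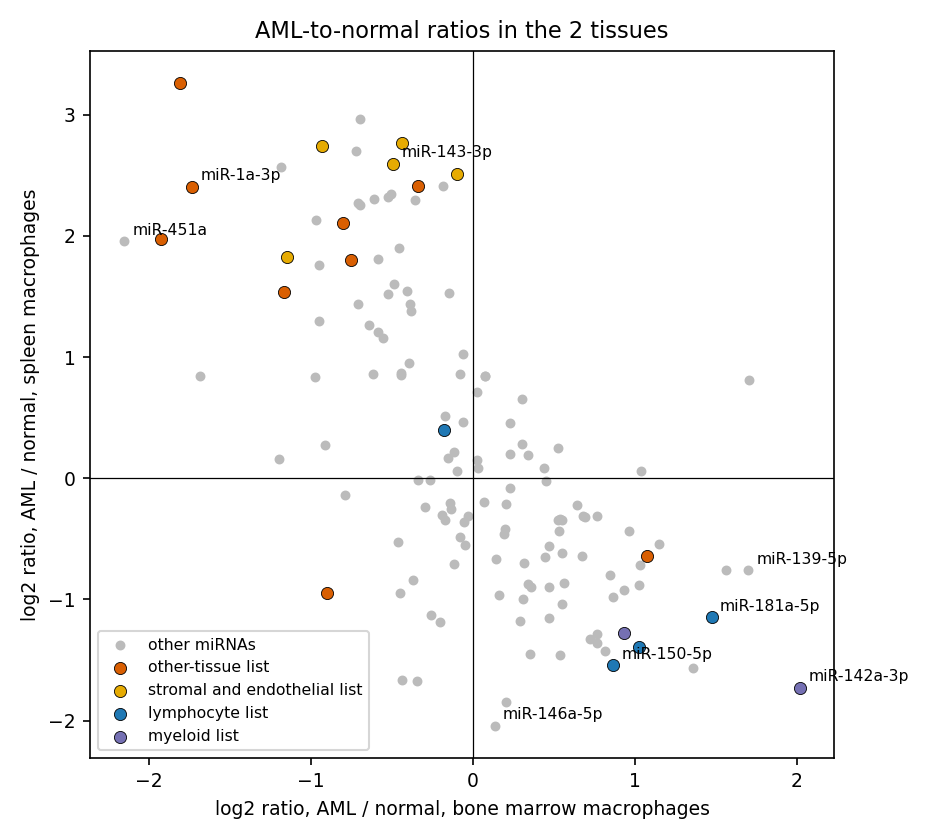
Each point is 1 of 144 miRNAs with at least 30 counts in every library, with the log2 ratio of AML to normal in BM macrophages on the x axis and in spleen macrophages on the y axis. Coloured points belong to 4 preset lists, and the points run from upper left to lower right, with r of -0.684.

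**Figure D3:**
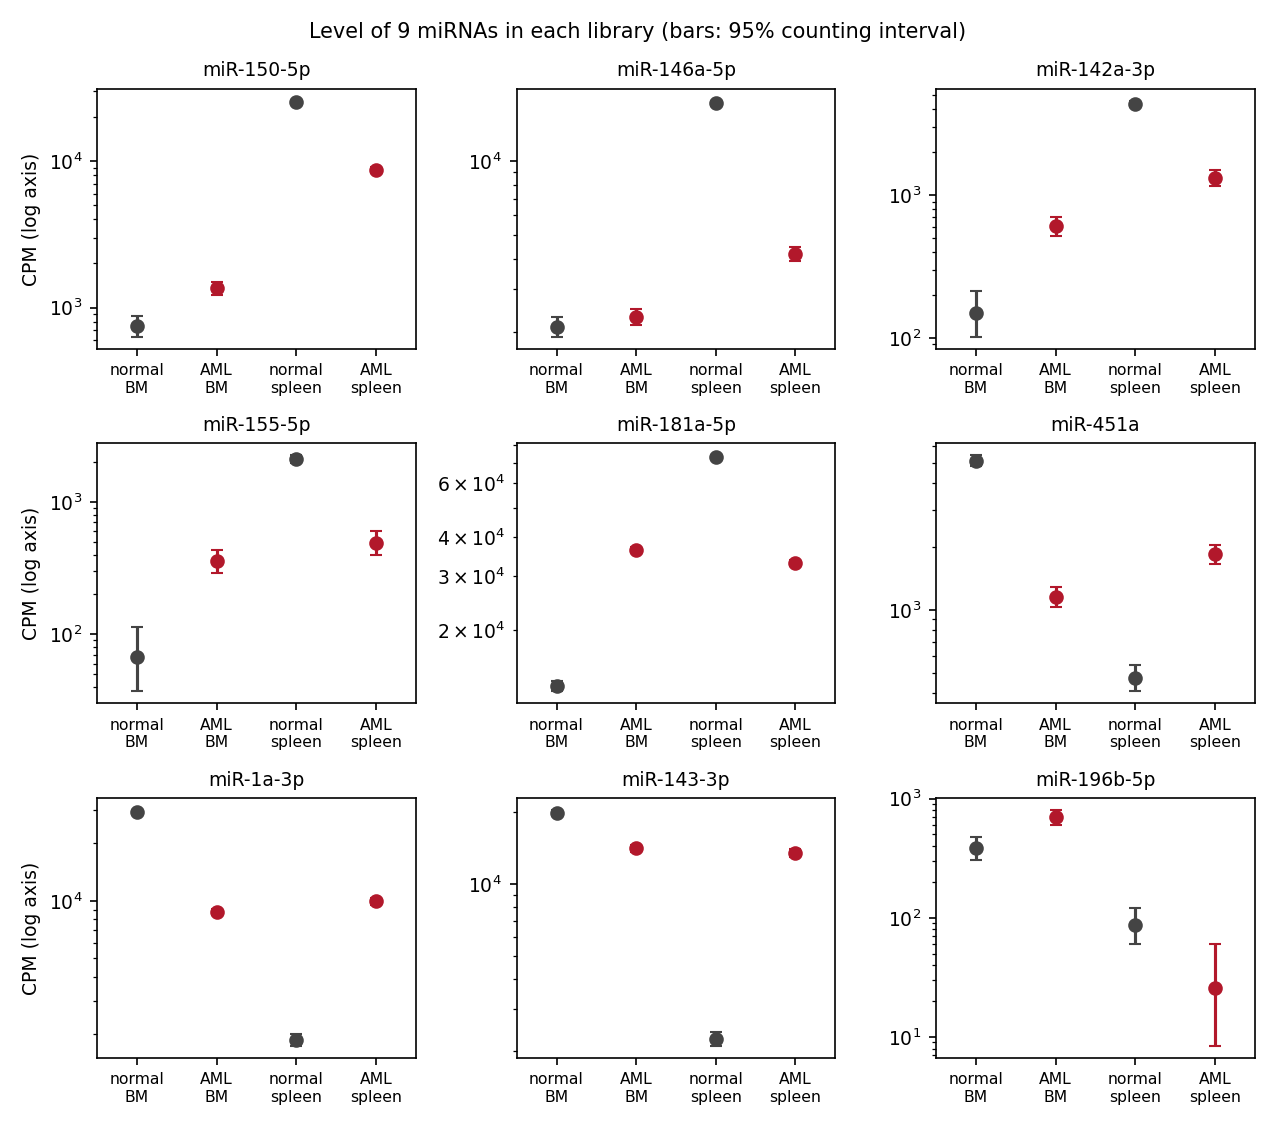
Level of 9 miRNAs, chosen after their values were seen, in the 4 libraries, in CPM on a log axis that does not start at 0. Points are single libraries, grey for normal and red for AML, and bars are 95% exact Poisson intervals for counting error. For example, miR-155-5p stood at 67.5 CPM in normal BM, 357 CPM in AML BM, 492 CPM in AML spleen and 2102 CPM in normal spleen.

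Normal spleen macrophages had higher miR-150-5p, miR-155-5p, miR-142a-3p and miR-146a-5p than normal BM macrophages and lower stromal, endothelial and muscle miRNAs. Of 234 miRNAs compared, 72 were at least 2-fold higher in the normal spleen library and 83 at least 2-fold lower, the most differences of the 4 comparisons. The direction of this split depended on the scaling, with 86 higher and 78 lower with DESeq2 size factors, 82 and 79 on totals without the 10 most abundant miRNAs, and 59 and 84 on total counts. The lymphocyte list had 4 of 5 members higher with a median log2 ratio of 2.24 (percentile 99.1), and the stromal and endothelial list had 9 of 9 members lower with a median of -3.15 (percentile 0.38). The comparison gives the tissue difference at homeostasis against which the AML libraries are set.

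Higher in normal spleen, miR-150-5p stood at 25275 CPM against 743 CPM, a log2 ratio of 5.09 [4.86 to 5.33], and miR-181a-5p at 73049 CPM against 13150 CPM, a log2 ratio of 2.47. The inflammation-induced miR-155-5p and miR-146a-5p were higher by 4.96 [4.21 to 5.84] and 3.03 [2.89 to 3.17], and miR-142a-3p and miR-142a-5p by 4.86 and 3.05. The highest log2 ratio among miRNAs with at least 100 counts was 5.45 [4.22 to 7.08], for miR-455-3p with 414 counts against 5. Higher too were miR-185-3p (4.90), miR-935 (4.25), miR-342-3p (3.70) and miR-5107-5p (3.01), and miR-5107-3p, with 67 counts against 0, was at least 11.8-fold higher. Reads of the lymphocyte list made up 9.46% of the normal spleen library and 1.69% of the normal BM library, and those of the myeloid list 0.646% and 0.0726%. Of 12 miR-17~92 family members, 4 were higher and 1 lower, with miR-92a-3p at 1.15.

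Lower in normal spleen, miR-3473b had a log2 ratio of -4.17 [-4.64 to -3.74], and the muscle miRNAs miR-133a-3p, miR-1a-3p and miR-206-3p stood at -3.99, -3.96 and -3.85. The other-tissue list had 9 of 11 members lower and a median of -3.47, below all 10000 random lists. The endothelial miR-126a-3p stood at -3.37, the stromal miR-143-3p at -3.15 and the erythroid miR-451a at -3.43 [-3.67 to -3.21], whereas miR-486a-5p was higher by 1.01. All 9 compared members of the blast and progenitor list were lower, with a median of -2.55 (percentile 1.99), among them miR-100-5p (-3.33), miR-10b-5p (-3.17), miR-10a-5p (-2.55) and miR-196b-5p (-2.15). In the miR-30 family 5 of 7 were lower, with miR-30a-5p at -3.09 and a list median of -1.87. The let-7 median was 0.04 with 2 higher and 1 lower of 9, the alternative activation median 0.04 with 1 higher and 1 lower of 5, and the miR-232724 median -0.07 with 2 lower of 7. The inflammation-induced median was -0.09 with 2 higher and 2 lower of 5, and each of these 4 medians changed sign under at least 1 other scaling. The miR-221, miR-222 and miR-34 list had 1 of 4 lower, miR-34c-5p at -2.40. All log2 ratios moved by 0.24 with DESeq2 size factors, by -0.16 on total counts and by 0.16 on totals without the 10 most abundant miRNAs. On total counts 13 of the 155 calls ended, among them those of miR-92a-3p (0.99), miR-106b-3p (0.93), miR-181b-5p (0.99) and miR-486a-5p (0.85). Of the 5 calls that ended with DESeq2 size factors, 1 was that of miR-223-5p, from -1.14 to -0.91, and it also ended on totals without the 10 most abundant miRNAs (-0.98).

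Between the leukaemic tissues, spleen macrophages had higher miR-150-5p and miR-150-3p and lower miR-196b-5p and miR-223-5p than BM macrophages. Of 211 miRNAs compared, 29 were at least 2-fold higher in the AML spleen library and 45 at least 2-fold lower. The stromal and endothelial list had 0 of 7 members different, with a median log2 ratio of -0.06 (percentile 56.5), and the miR-17~92 family had 4 of 11 lower with a median of -0.76 (percentile 3.07).

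The highest log2 ratio in this comparison among miRNAs with at least 100 counts was 4.36 [3.88 to 4.88] for miR-5107-5p, with 537 and 38 counts. The lymphocyte miR-150-5p and miR-150-3p were higher in AML spleen by 2.68 [2.52 to 2.85] and 2.82 [2.51 to 3.15], and miR-342-3p by 2.37. Their list also held miR-181d-5p and miR-181b-5p, lower at -3.14 and -1.27, so the lymphocyte list had 2 members higher and 2 lower and a median of -0.14. The lowest was miR-196b-5p, with 5 counts in AML spleen and 196 in AML BM, a log2 ratio of -4.75 [-6.39 to -3.51]. The myeloid miR-223-5p stood at -3.36 [-4.45 to -2.44] whereas miR-142a-3p was higher by 1.11, and miR-142a-5p was neither. With 0 counts against 39, miR-10b-3p was lower with a bound of -3.16 against 3 counts, and with miR-196b-5p and miR-10a-3p made the 3 lower members of the 10 in the blast and progenitor list (median -0.60). Also lower were miR-3473b (-3.09), miR-125a-5p (-1.88), miR-130b-5p (-1.88), miR-25-5p (-1.85), miR-146b-5p (-1.83) and miR-222-3p (-1.51). The other-tissue list had 1 member higher (miR-133a-3p, 1.09) and 1 lower (miR-128-3p, -1.20) of 9. Its read share was 2.72% in AML BM and 2.58% in AML spleen. The miR-30 and miR-232724 lists had 0 members different, with medians of -0.24 and -0.02, the latter changing sign under other scalings.

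Some lists were thinly covered. The miR-29 family had 2 members compared in AML BM against normal BM, with miR-29a-3p at -0.45 there and at -0.95 between the spleen libraries. The Dlk1-Dio3 list had 1, miR-127-3p, which was lower in normal spleen than in normal BM (-1.94). This list did not hold miR-381-3p, named above as a miRNA of the same region. The hypoxia list had none, since miR-210-3p had between 1 and 21 counts per library. The erythroid list held 4 compared members in the BM comparison and 3 in the spleen comparison, and its read share lay between 1.41% and 1.67% in the 4 libraries.

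Genome positions of hairpins, matched by name to the GENCODE annotation of GRCm38, were as follows. The hairpin of miR-155 lies on chromosome 16 from 84714140 to 84714204 (+), in an exon of the long non-coding RNA gene Mir155hg. The hairpin of miR-150 lies on chromosome 7 from 45121757 to 45121821 (+), with no gene overlapping on the same strand, and that of miR-139 on chromosome 7 from 101475376 to 101475443 (+), in an intron of Pde2a. The hairpin of miR-451a lies on chromosome 11 from 78073170 to 78073241 (+), next to that of miR-144 from 78073005 to 78073070. The hairpin of miR-126a lies on chromosome 2 from 26591357 to 26591429 (+), in an exon of an Egfl7 transcript, and those of miR-143 and miR-145a on chromosome 18 from 61649196 to 61649258 and from 61647825 to 61647894 (-). The hairpin of miR-196b lies on chromosome 6 from 52230081 to 52230165 (-), in an exon of a Hoxa9 transcript, and that of miR-10b on chromosome 2 from 74726070 to 74726137 (+), in introns of Hoxd3 and Hoxd4 transcripts. The hairpin of miR-5107 lies on chromosome 18 from 60812076 to 60812163 (+), in an exon of Cd74, which encodes the invariant chain of MHC class II.

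A model with state and tissue as additive terms used the libraries of 1 tissue as partners of the other, with 2 libraries per state and 1 residual degree of freedom. For AML against normal, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 246 miRNAs, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998. The lowest unadjusted p-values in this edgeR test were 0.0699 for miR-204-5p, lower in AML, and 0.0711 for miR-3470b, higher in AML with a log2 fold change of 2.17. For miR-204-5p the counts were 38 in normal BM and 7 in AML BM, but only 3 in normal spleen and 0 in AML spleen. DESeq2 and limma-trend also called 0. For spleen against BM the edgeR test called 0, with 15 at an unadjusted p under 0.05 and a smallest adjusted p of 0.606, limma-trend called 0 and DESeq2's Wald test called 4 higher and 4 lower. The lowest unadjusted p-values in the edgeR tissue test were 0.0179 for miR-3473b (log2 fold change -3.63) and 0.0187 for miR-5107-5p (3.68), apart from the rows miR-5107-3p, miR-10b-3p and a predicted miRNA, for which 1 or more libraries held 3 counts or fewer. Adjusted over the list alone, 0 members of each list passed for AML and for tissue. The common dispersion was 0.417, a biological coefficient of variation of 0.646, and it took up the opposite directions of the tissues as noise.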

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

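The tests in this part were chosen after the opposite ratios and the shared movement of other-tissue miRNAs had been seen, except for the correlation and the counts of shared calls, which were planned. The AML-to-normal ratio differed between BM and spleen for many miRNAs: 20 miRNAs were at least 2-fold different in both tissues and opposite in direction, and the correlation across miRNAs was -0.684. The difference between tissues was not tested against replicates, since each group had 1 library. On the log2 scale, the AML ratio in spleen exceeded that in BM by 4.11 for miR-451a, 3.90 for miR-206-3p, 5.08 for miR-133a-3p, 4.14 for miR-1a-3p and its shared-read row miR-1b-5p, 3.75 for miR-9-5p, 2.70 for miR-122-5p and 5.23 for miR-6538. The gap was -2.62 for miR-181a-5p, -2.42 for miR-181b-5p, -4.49 for miR-155-5p, -3.75 for miR-142a-3p and its shared-read row miR-142b, -6.57 for miR-185-3p and -4.54 for miR-92a-1-5p.

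For the opposite directions as a whole, exchanging the AML BM and AML spleen libraries left r at -0.778 across 144 miRNAs. Exchanged AML labels would thus not remove the pattern. The AML libraries lay closer to each other (r of 0.918 in log2 levels) than the normal libraries did (0.674). A negative r under either pairing goes with that layout, so the exchange cannot tell whether the labels are right. Nor does r alone show that leukaemia acts differently on the 2 tissues. A trend with the GC content of the hairpin arm is argued against as the whole cause. Removing it from both ratios left r at -0.665 over the 134 miRNAs with a matched hairpin, against -0.680 before. A differing share of RNA from non-haematopoietic cells could dilute haematopoietic miRNAs by 1 factor per library. The medians of the myeloid and lymphocyte lists lay 0.53 apart in AML BM against normal BM, within the SD of the lymphocyte members of 0.609. With 3 and 5 members, this gap cannot decide the question. The 5 lymphocyte members ranged from -0.18 (miR-150-3p) to 1.47 (miR-181a-5p) there, and from -2.78 (miR-181d-5p) to 0.40 (miR-150-3p) between the spleen libraries. In AML BM the intervals of miR-181a-5p and miR-181b-5p given above do not overlap. Beyond counting error, the members of this list thus did not move by 1 factor. With 1 library per group the spread between libraries is unknown, so these values cannot exclude 1 factor as the sole cause. Dilution, as the whole or a part of the cause, cannot be told apart from a change in the macrophages. Leukaemia acting differently on BM and spleen macrophages stays open too, untested.

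Other-tissue and stromal miRNAs moved together, lowest in normal spleen and highest in normal BM by read share. A single outside source of RNA would move them by 1 factor only if the sorted cells themselves held none of them. In AML BM against normal BM the medians of 3 muscle miRNAs (miR-1a-3p, miR-133a-3p, miR-206-3p) and of the stromal and endothelial list lay -1.04 apart. This was only just beyond the SD of the stromal members, 0.979. In normal spleen against normal BM they lay -0.81 apart with an SD of 0.761. Whether the sorted cells express part of the stromal list is not known, so neither gap can decide for or against a single source. The gap was -0.26 in AML spleen against normal spleen and 0.24 in AML spleen against AML BM. These lay within the SD of the muscle miRNAs, 0.655 and 0.566, a spread too wide for them to decide. For the muscle miRNAs alone, skeletal muscle RNA in differing amounts is a candidate explanation: over the 4 libraries the ratios of miR-206-3p and miR-133a-3p to miR-1a-3p ranged over at most 0.91 on the log2 scale, while the level of miR-1a-3p ranged over 3.96. The departure came from AML spleen, with 9.85 reads of miR-133a-3p per 100 of miR-1a-3p against 5.26 to 5.54 in the other libraries. Expression of these miRNAs in the sorted cells, and a difference between tissues or states, stay open and were not tested; a macrophage sort would remove muscle cells but not necessarily their free RNA.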

How the results depend on the processing

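Collapsed shared-read rows, libraries thinned to 180227 reads, omission of other-tissue and stromal miRNAs, and a minimum of 300 counts in every library for the correlation were chosen after the data were seen. The correlation kept its sign under every setting run. The balance of higher against lower calls did not. In AML BM against normal BM it turned from 29 and 26 to 55 and 64 with a minimum of 1 count, 12 and 15 with the whole interval beyond 2-fold, and 23 and 25 thinned. In AML spleen against normal spleen it turned from 54 and 46 to 51 and 68 with DESeq2 size factors and 40 and 43 without other-tissue and stromal miRNAs. In normal spleen against normal BM it turned from 72 and 83 to 86 and 78 with DESeq2 size factors, 82 and 79 without the 10 most abundant, 49 and 47 at 100 counts and 65 and 63 without other-tissue and stromal miRNAs. In AML spleen against AML BM it turned from 29 and 45 to 74 and 67 with a minimum of 1 count. Of single counts and values, 104 stayed within the main interval or within 1.5 times the main count while 25 moved. The 104 include r under other scalings, which cannot change. They also include counts of 0 from the additive model, which recovered 0% of simulated changes at the estimated dispersion. The tally therefore overstates how stable the calls are. Values of r were judged by the resampled interval given above, which is not a confidence interval. Of list medians and log2 ratios of named miRNAs under other scalings, 526 stayed within their counting interval, 158 moved, and no called ratio changed sign, although between 0 and 13 calls of a comparison ended under a scaling, some of them of miRNAs named in the results. List medians near 0 that changed sign are named with their comparison in the results, apart from those of the alternative activation and the miR-221, miR-222 and miR-34 lists in AML spleen against AML BM (0.03 and -0.04). Scaling leaves r at -0.684 by construction. The correlation was -0.670 with shared-read rows collapsed, -0.653 thinned, -0.644 without other-tissue and stromal miRNAs and -0.637 at 300 counts.

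With a minimum of 1 count, more miRNAs enter: 55 higher and 64 lower in AML BM against normal BM, 117 higher in AML spleen against normal spleen, 159 lower in normal spleen against normal BM, 74 higher in AML spleen against AML BM, an r of -0.40 and 120 miRNAs with a 4-fold gap between tissues. With a minimum of 100 counts, fewer enter: 15 higher and 9 lower in AML BM, 33 higher in AML spleen, 47 lower in normal spleen, 16 higher and 21 lower in AML spleen against AML BM, an r of -0.713, a same-direction share of 0% and 45 with a 4-fold gap. With the whole interval beyond 2-fold, a stricter rule, counts were 12 higher and 15 lower in AML BM, 26 lower in AML spleen against normal spleen, 45 higher in normal spleen, and 11 higher and 23 lower in AML spleen against AML BM. The same-direction share of 4.76% was 0% in thinned libraries, 9.09% on total counts and 10.9% with a minimum of 1 count, and between 4.17% and 5.88% with the other scalings, collapsed rows and other-tissue miRNAs left out. DESeq2's Wald test called 4 miRNAs higher and 4 lower for tissue against 0 with edgeR, and the cause was not tested.

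Leaving out a library was not run, since a pair then has no partner and the additive model no residual degrees of freedom. No replicate block was fitted, since each group has 1 library and the labels carry no replicate numbers. The additive model, with tissue as a term, paired libraries by tissue only. Depth limits what can be said of miRNAs under 30 counts, which were not called.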

Other observations

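The miRNAs in this part were chosen after their values were seen. For miR-223, a myeloid hairpin, the 5p arm outnumbered the 3p arm in all 4 libraries, by 4.20 times in normal BM, 1.29 in normal spleen, 12.4 in AML BM and 2.5 in AML spleen, from 10, 28, 12 and 4 counts of miR-223-3p. How the authors' counting treated the 3p reads, and how fully the RNA extraction recovered small RNA, are not given in the sources used here, so these counts do not by themselves give the proportion of the arms in the cells. For miR-150, the 5p arm was 25275 CPM in normal spleen and 8687 CPM in AML spleen, while the 3p arm was 1892 CPM and 2493 CPM.

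The reads of miR-5107, whose hairpin lies in an exon of Cd74, were higher in spleen in both states: miR-5107-5p stood at 1436 CPM in normal spleen and 2783 CPM in AML spleen, against 178 CPM in normal BM and 136 CPM in AML BM. Between the spleen libraries its log2 ratio was 0.95 [0.78 to 1.13], below 2-fold. The 3p arm had 67 and 27 counts in the spleen libraries and 0 in both BM libraries. In contrast, miR-3473b stood at 2160 CPM in normal BM and 2072 CPM in AML BM, against 120 CPM in normal spleen and 244 CPM in AML spleen, where it was higher than in normal spleen by 1.02 [0.41 to 1.64], and by 0.78 with DESeq2 size factors, below 2-fold. Of miRNAs in different lists, miR-10b-5p ran beside the stromal miR-143-3p at 74.7, 73.6, 63.7 and 79.2 reads per 100 of miR-143-3p in normal BM, normal spleen, AML BM and AML spleen. Likewise miR-192-5p had between 76.4 and 92.3 reads per 100 of miR-200a-3p. Over 134 miRNAs, the Spearman correlation of the log2 ratio with the GC content of the hairpin arm was 0.30 for AML BM against normal BM, -0.18 for AML spleen against normal spleen, 0.26 for normal spleen against normal BM and 0.01 for AML spleen against AML BM.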
